A study of Gallus gallus with 2 samples.

How the data were processed

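Brain RNA of newly hatched chicks was pooled by sex and condition, and each array was hybridised with a trained pool in Cy3 and a dark-reared pool in Cy5, per the labels. The sample titles give the groups in the other order, and the direction used here follows the dye labels. The deposited scanner tables hold the mean spot intensity and the median background intensity of each probe and channel without normalization. Their processed intensity had been detrended and dye-normalized by a linear factor and LOWESS, with a surrogate in place of low signals, per the file headers. A surrogate was used for 25.2% of probes on the female and 26.0% on the male array. The deposited log10 ratio is of red over green, and the p-value beside it is the software's spot-level value, per the file headers. The log10 ratio is exactly 0 for 18.5% of probes in females and 19.6% in males. The deposited series table holds log2 ratios that equal green over red processed signals, trained over dark-reared, with medians of 0.067 and 0.082. The scanner software's version is 9.5.3.1 in the file headers and 8.5.1.1 in the submitters' notes. Observed spike-in ratios had a slope of 0.936 and 0.942 on the intended ones.

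Mean signals were corrected for background with normexp (offset 50) and normalized within arrays by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with data.table (version 1.17.8). The 25 probes with an outlier flag were left out. A probe was kept if well above background in at least 1 channel on both arrays, which left 27372 of 42034 probes, and 25207 probes were so in both channels on both arrays.

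The training comparison used limma (lmFit and eBayes) on the ratios of both arrays, with Benjamini-Hochberg adjustment over the kept probes, 1 residual degree of freedom per probe and 5.06 prior degrees of freedom. The sexes served as replicates, so the p-values measure the spread between 2 arrays, including any sex difference, and a dye effect shared by the arrays passes as a shift. Each sex alone was described by probes at least 1.5-fold changed. The 28 gene lists were tested with camera at an inter-gene correlation of 0.01, with the brightest probe per gene (7347 genes), and list medians were ranked among 10000 random lists matched in 20 intensity bins. Of the listed genes measured, 23 stand on more than 1 list. For the sexes, channel values were normalized by loess and Aquantile and differences taken within each condition, with no test. A bound for a gene not well above background in 1 sex sets each dim value to at least the lowest value that was well above background in that channel and array. Each ratio pairs the trained and the dark-reared pool of 1 sex within its array.

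Probes were named by RefSeq accession (5150), gene number (3534) or array symbol (892) through a table of assembly GRCg7b, or kept the array's symbol (216), and 32242 stayed unnamed. Coordinates and chromosomes are those of galGal2. The plan named the reference as the source of the Z and W probes, and galGal2 was used in its place because the builds differ.

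The gene lists, the tests of each comparison and the rule for named genes were set before the data were examined. Older symbols on the lists were matched to their current names, a step added once the probe names had been seen. The rule takes the 12 largest means in each direction past adjusted p 0.05 among genes well above background in both channels on both arrays, the 2 largest shifts of each list and up to 2 more that passed, and DIO2, DIO3, NME2, FOS, EGR1, ARC, JUN and BDNF. It also takes the 5 largest differences in response and the 6 largest differences between the sexes in each direction. Where 5 or fewer members of a list passed in a direction, the members outside the rule, 36 genes, were chosen after their values were seen, among them ADCYAP1, AQP4, CALB2, CELF4, CHGB, DCX, DNAJA4, DUSP1, ENO1, GAPDH, GJA1, GRP, HERPUD1, HSPA9, HSPD1, KLF1, LHX2, MAP1A, NCAM1, NCOA1, NDUFA5, NDUFA9, NDUFAB1, NDUFB6, NDUFB8, NR3C2, PCSK2, PDGFA, PVALB, RPL3, RPL35A, RPLP2, SGK1, TGFB3 and TUBB4B. The results of some genes are not reported here. Genes with both probes past the test were also chosen after their values were seen.

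The steps were tested on simulated data for 27372 probes. Limma recovered 10 of 67 probes changed 1.25-fold, 65 of 67 changed 1.5-fold and 66 of 66 changed 2-fold, with 10 false calls, and made 0 calls when none was changed. With many probes changed 1.25-fold it recovered 7683 of 8212, with 315 false calls. The simulated noise was drawn independently for each array. These runs therefore do not cover false calls from a dye or probe effect that both arrays share. A 2-fold excess given to the trained channel of 200 spots came out higher in all 200, with a median of 0.76 where 1 was put in on the log2 scale. Alternatives changed the background correction, the values, the normalization, the filter, the moderation, the unit tested, the thresholds, the direction of the dyes, the inter-gene correlation and the scaling between arrays.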

Results

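Filial imprinting is the learning by which a newly hatched chick comes to follow a conspicuous object seen early in life. Gene expression in the brain was compared between newly hatched Cobb chicks trained for 1 h and chicks kept in the dark. The only comparison group was kept in the dark, so learning cannot be told apart from seeing light or from other parts of the training session. Each condition had 16 chicks, and the RNA was combined into 4 pools of 8 chicks, a pool for each sex and condition. Each sex had a single 2-colour array on which the trained pool carried Cy3 and the dark-reared pool Cy5. Of 42034 probes, 62.9% were well above background in the trained and 66.5% in the dark-reared channel of the female array, and 61.5% and 66.4% in those of the male array. None of the probes was saturated. Ratios are log2 of trained over dark-reared, and means over both arrays are given with their SD (n = 2 arrays) where stated. The number of arrays limits the precision. The dyes were not swapped, so a dye effect of a probe adds to its ratio in the same direction on both arrays.

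The first comparison asked which transcripts differed in the brain after training, with both sexes as replicates. The iodothyronine deiodinases moved in opposite directions: DIO2, which makes the active thyroid hormone, rose 1.92-fold (log2 0.94 ± 0.071, SD, n = 2), and DIO3, which inactivates the hormone, fell by 0.65 on the log2 scale (SD 0.033, n = 2). The pyruvate dehydrogenase kinase PDK4 rose 2.17-fold (log2 1.12 ± 0.024, SD, n = 2). The salt-inducible kinase SIK1 rose 2.00-fold (log2 1.00 ± 0.17, SD, n = 2). EGR1, a transcription factor induced by neuronal activity, rose 1.47-fold (log2 0.56 ± 0.13, SD, n = 2), and the neurotrophin BDNF rose 1.40-fold (log2 0.49 ± 0.050, SD, n = 2). With median centring in place of loess BDNF lay below 0. That setting left the kept probes with medians of -0.30 in females and -0.39 in males. The histone deacetylase HDAC11 fell by 1.01 on the log2 scale (SD 0.087, n = 2). DIO2, PDK4, SIK1, EGR1, BDNF and HDAC11 each had a single kept probe. A probe-specific effect on these genes could therefore not be checked against another probe. The processed signals gave means of 1.01 for EGR1 and -0.98 for DIO3, more than 1.5 times as large. In limma's test over the arrays, adjusted p was 0.00470 for PDK4, 0.00697 for DIO2, SIK1 and HDAC11, 0.00719 for DIO3, 0.00839 for BDNF and 0.00853 for EGR1.

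On the galGal2 build of the array design, the DIO2 probe lies on chromosome 5 from 37376448 to 37376507 and the DIO3 probe on the same chromosome from 46106415 to 46106474. The PDK4 probe lies on chromosome 2 from 23211638 to 23211697, the SIK1 probe on chromosome 1 from 103586106 to 103586165 and the HDAC11 probe on chromosome 12 from 5780432 to 5780491. The EGR1 probe spans 17261035 to 17261211 on chromosome 13, and the BDNF probe 44774438 to 44774497 on chromosome 3. Exons and untranslated regions were not analysed here.

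Of 27372 probes kept, 1726 were higher and 3074 lower in trained chicks at limma's adjusted p of 0.05. Their median size was 0.30 on the log2 scale, and 191 of the 4800 probes reached 1.5-fold. With a normexp offset of 16 in place of 50 the counts were 306 and 628, and 87 of 143 named genes no longer passed. Median centring in place of loess, which sets the median over all probes of an array to 0, gave 974 and 16499. The kept probes then had medians of -0.30 in females and -0.39 in males. A mean below 0 in that setting can therefore still lie above the medians of the kept probes. A gene symbol was known for 1629 of the probes called as reported. Among named genes past adjusted p 0.05, other large positive means were those of the kinase NUAK2 (0.96), PLEKHB1 (0.83), the metallothionein MT4 (0.82), TULP1 (0.79) and the cAMP-inducible repressor ICER (0.73). YWHAE, a 14-3-3 protein (0.63), the glucocorticoid-induced FKBP5 (0.62), the Wnt receptor FZD3 (0.61) and ZSWIM5 (0.59) followed. Other large negative means were those of PEBP1 (-0.93), the primase subunit PRIM2 (-0.89), the splicing kinase CLK4 (-0.86), VSIG10 (-0.85), SDHAF4 (-0.83) and CD248 (-0.81). BASP1, a growth cone protein (-0.78), ASB5 (-0.77), TCTEX1D2 (-0.77), NUDT7 (-0.77) and WRAP73 (-0.76) followed. These genes passed adjusted p 0.05 and had the same sign on both arrays. The other probe of CLK4 and that of NUDT7 were also lower, whereas that of PEBP1 had the opposite sign. In the processed signals TULP1 (1.81 and 1.56 in females and males) lay above PDK4 (1.30 and 1.34), and CD248 (-1.34 and -1.29) below HDAC11 (-0.80 and -0.64). FOS and NME2 were not well above background in either channel of either array. MT4, YWHAE, FKBP5 and ZSWIM5 lay below 0 with median centring in place of loess. Processed signals gave a mean more than 1.5 times smaller for PEBP1, CLK4, VSIG10, BASP1, TCTEX1D2 and NUDT7 and larger for TULP1, FZD3 and CD248.

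With the scanner software's processed signals, limma called 0 probes (smallest adjusted p = 0.261, and 4878 probes at an unadjusted p under 0.05), while 85.7% of the 4800 probes kept their sign on both arrays. Across 648 genes with non-overlapping probes, which are not independent replicates, the ratios of the same probe on both arrays correlated at r = 0.72 and those of different probes of a gene at r = 0.12 (95% bootstrap interval 0.041 to 0.21).

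**Figure D1:**
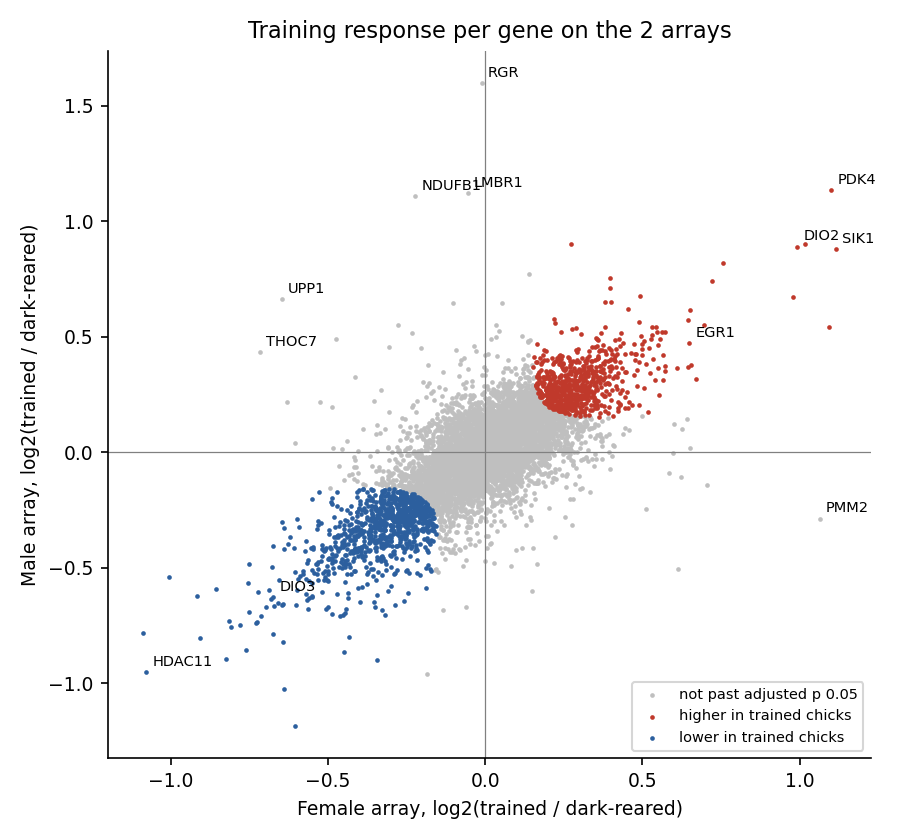
Each point is a gene, by its brightest probe, with the log2 ratio of trained over dark-reared chicks on the female array (x axis) and on the male array (y axis), coloured by limma's call over both arrays. PDK4 and DIO2 lie high and HDAC11 and DIO3 low on both axes, and RGR lies at -0.011 on the female and 1.60 on the male axis.

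**Figure D2:**
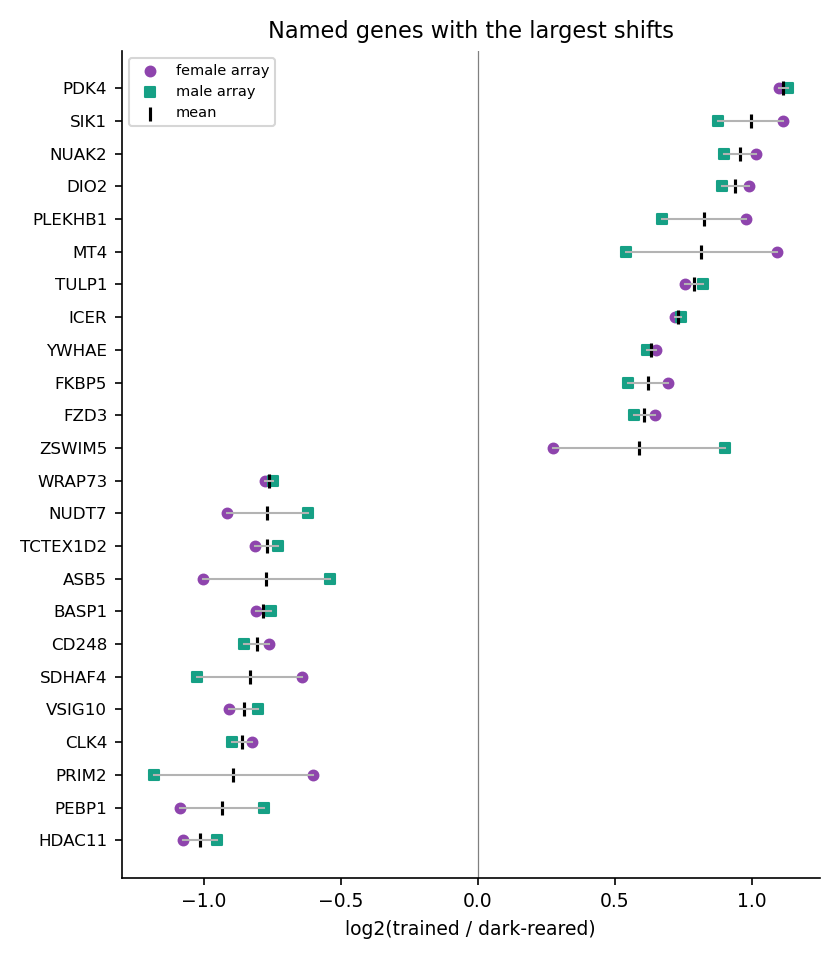
The 12 genes with the largest positive and the 12 with the largest negative mean log2 ratio (x axis) among named genes past adjusted p 0.05 and well above background in both channels on both arrays, with circles for the female array, squares for the male array and a tick for the mean. Means run, in an order that the processed signals change, from -1.01 for HDAC11 to 1.12 for PDK4.

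Gene lists fixed beforehand were then examined for shared shifts. Of the 8242 kept probes with a gene symbol 1629 passed the test. Members of a list can therefore pass without a shift shared by the list, which holds for each list below. Immediate early and activity-regulated genes went both ways: 10 of 27 measured members rose, 8 fell and 9 did not pass (11 higher and 9 lower adjusted over the list alone). Members past the test made up 66.7% of the list, the largest share of any list. The list's median of 0.057 lay above that of 90.26% of random lists matched on intensity, and of 96.81% in females and 99.25% in males. Camera did not call the list, whose median was 0.14 in the processed signals and -0.52 with median centring. SIK1, EGR1 and BDNF rose, while KLF6 (-0.52) and NFIL3, both transcription factors, fell. CYR61 had ratios of -0.18 and -0.96 in females and males and did not pass, and ARC (-0.023) and JUN (-0.0012) lay near 0. In the thyroid hormone list 2 of 14 rose, DIO2 and the hormone-binding CRYM (0.26), and 3 fell, DIO3 and the nuclear receptor cofactors NCOR1 (-0.34) and NCOA1 (-0.25) (2 higher and 3 lower adjusted over the list alone). Its median was -0.017, its mean 0.0015 and its test pointed down. BDNF and CRYM lay below 0 with median centring in place of loess, and the software's processed signals put NCOR1 and NCOA1 above 0. The mean was, in the processed signals, more than 1.5 times smaller for KLF6 and NFIL3.

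Cytosolic ribosomal protein genes were lower as a list, with 13 of 37 members lower, 3 higher and 21 not past the test (3 higher and 15 lower adjusted over the list alone). The list's mean was -0.17 and its median -0.10 (camera adjusted p = 0.00361 over 28 lists, and adjusted p = 0.999 with an estimated correlation). RPL32 (-0.73), RPS2 (-0.63), RPS23 (-0.59) and RPL14 (-0.58) fell, while RPL3 (0.29), RPLP2 (0.23) and RPL35A (0.22) rose. In females and males the processed signals gave -0.25 and -0.24 for RPL32, -0.35 and -0.43 for RPS2, -0.42 and -0.47 for RPS23 and -0.12 and -0.26 for RPL14. The list's median lay above that of 4.50% of random lists matched on intensity, and of 0.450% in females and 6.99% in males. RPL3, RPLP2 and RPL35A lay below 0 with median centring in place of loess. Processed signals gave a mean more than 1.5 times smaller for RPL32, RPS2, RPL14 and RPL3. None of the other 27 lists passed camera, each with an adjusted p of 0.998, and 0 of them had an unadjusted p under 0.05.

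Of 14 glucocorticoid and stress genes 4 rose, PDK4, FKBP5, the releasing hormone CRH (0.46) and SGK1 (0.29), and 3 fell, the receptors CRHR2 (-0.40) and NR3C2 (-0.24) and the phosphatase DUSP1 (-0.30) (6 higher and 3 lower adjusted over the list alone). Of 25 neuropeptide genes 5 rose, CCK (0.51), CRH, ADCYAP1 (0.35) and GRP (0.32) and the convertase PCSK2 (0.24), and 3 fell, NTS (-0.43), GAL (-0.43) and CHGB (-0.34) (5 higher and 4 lower adjusted over the list alone). The median of that list was -0.021, its mean 0.016 and its test pointed up. Of 38 neurotrophin and growth factor genes 6 rose, among them PDGFB (0.54), BDNF and the receptors NTRK3 (0.28) and NTRK2 (0.22), and 3 fell, IGFBP4 (-0.30), PDGFA (-0.25) and TGFB3 (-0.20) (7 higher and 3 lower adjusted over the list alone). Of 13 circadian clock genes NR1D2 (0.47) rose and CLOCK (-0.24) and NFIL3 (-0.24) fell (1 higher and 2 lower adjusted over the list alone), and their median of 0.013 and mean of 0.0059 were above 0 while the test pointed down. FKBP5, CRH, SGK1, CCK, ADCYAP1, GRP, PCSK2, PDGFB, NTRK3, NTRK2 and NR1D2 lay below 0 with median centring in place of loess, and the software's processed signals put NTS, CHGB, IGFBP4 and TGFB3 above 0. The mean was, in the processed signals, more than 1.5 times smaller for SGK1, CRHR2, NR3C2, DUSP1, PDGFB, NTRK2, CLOCK and NFIL3 and larger for GAL.

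In the microtubule and growth cone list 6 of 23 fell, among them BASP1, the tubulin TUBB2B (-0.66) and the stathmins STMN1 (-0.56) and STMN2 (-0.39), and 4 rose, DCX (0.36), NCAM1 (0.34), TUBB4B (0.29) and MAP1A (0.21) (5 higher and 6 lower adjusted over the list alone). Its median was 0.043, its mean -0.044 and its test pointed down. Of 20 glutamate receptor and postsynaptic genes CACNG3 (0.31) and CAMK2B (0.26) rose and the AMPA receptor subunit GRIA4 (-0.45) and PPP3R1 (-0.28) fell (2 higher and 2 lower adjusted over the list alone). Of 15 GABA and glycine genes 4 fell, among them the receptor subunit GABRA3 (-0.38), the GABA-synthesizing GAD1 (-0.32) and the glycine transporter SLC6A9 (-0.24) (1 higher and 4 lower adjusted over the list alone). Of 19 synaptic vesicle genes SYT4 (0.21) rose, RAB3B (-0.23) fell and DNM1 (0.25) did not pass (0 higher and 0 lower adjusted over the list alone). Of 16 monoamine and acetylcholine genes the dopamine receptor DRD5 (0.21) rose and the noradrenaline transporter SLC6A2 (-0.24) did not pass (0 higher and 0 lower adjusted over the list alone). Of the 3 other probes of DCX and of MAP1A, 1 each had the opposite sign. DCX, NCAM1, TUBB4B, MAP1A, CACNG3, CAMK2B, SYT4, DNM1 and DRD5 lay below 0 with median centring in place of loess, and the software's processed signals put GABRA3 and GAD1 above 0. Processed signals gave a mean more than 1.5 times smaller for TUBB2B, GRIA4, PPP3R1, SYT4, RAB3B and DRD5.

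In the oxidative phosphorylation list 6 of 33 fell, among them NDUFB10 (-0.60), ATP5O (-0.46), SDHA (-0.44) and CYCS (-0.42), and 5 complex I subunit genes rose, NDUFA9 (0.32), NDUFB6 (0.30), NDUFA5 (0.25) and NDUFAB1 (0.24) and NDUFB8, whose dark-reared signal was not well above background on either array (5 higher and 8 lower adjusted over the list alone). Its median was 0.010, its mean -0.022 and its test pointed down. Of 24 glycolysis and hypoxia genes PGAM1 (0.41) rose and 5 fell, ADM (-0.51), PDK3 (-0.36), BNIP3 (-0.32) and ENO1 (-0.27) and GAPDH (-0.31), which the processed signals put above 0 (2 higher and 7 lower adjusted over the list alone). Of 25 heat shock and unfolded protein genes 3 rose, PDIA3 (0.44), HSPA9 (0.30) and HERPUD1 (0.27), and 5 fell, DNAJA1 (-0.50), CANX (-0.43), CHORDC1 (-0.34), HSPD1 (-0.33) and DNAJA4 (-0.22) (6 higher and 6 lower adjusted over the list alone). Of 19 lipid synthesis genes ACLY (0.44) and FDPS (0.40) rose and HMGCS1 (-0.27) and MVD (-0.27) fell (2 higher and 2 lower adjusted over the list alone), with a median of -0.0039, a mean of 0.0063 and a test that pointed down. Of 37 cell cycle genes CENPF (-0.22) fell and BUB1 (0.20) did not pass (0 higher and 0 lower adjusted over the list alone). Of 24 interferon and inflammatory genes NFKB2 (0.26) and SOCS1 (0.24) rose and IFI35 (-0.29) and TAP2 (-0.25) fell (4 higher and 3 lower adjusted over the list alone). The other probe of SOCS1 and that of HERPUD1 had the opposite sign. NDUFA9, NDUFB6, NDUFA5, NDUFAB1, PGAM1, PDIA3, HSPA9, HERPUD1, FDPS, NFKB2 and SOCS1 lay below 0 with median centring in place of loess, and the software's processed signals put GAPDH, HMGCS1, MVD, CENPF and IFI35 above 0. The mean was, in the processed signals, more than 1.5 times smaller for NDUFB10, ATP5O, SDHA, CYCS, NDUFA9, ADM, BNIP3, HSPA9, DNAJA1, CANX, HSPD1 and TAP2 and larger for ACLY and SOCS1.

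Of 11 oligodendrocyte markers MBP (-0.62) and ASPA (-0.44) fell and TF (0.31) and CNP (0.26) rose (4 higher and 3 lower adjusted over the list alone). Of 12 astrocyte markers HES5 (-0.27), GLUL (-0.27), S100B (-0.22) and GJA1 (-0.21) fell and NTRK2 (0.22) and AQP4 (0.21) rose (2 higher and 5 lower adjusted over the list alone). Of 22 vascular and mural markers 4 fell, VWF (-0.71), SOX18 (-0.67), COL4A1 (-0.45) and CLDN5 (-0.23), and 0 rose (2 higher and 6 lower adjusted over the list alone). Of 12 genes on the list of blood cell markers the globin HBBA (0.41) and IFRD1 (0.37) rose. CA2 (-0.40), EPB42 (-0.27) and KLF1 (-0.25) on that list fell (4 higher and 4 lower adjusted over the list alone). Whether the genes of that list mark blood cells in this tissue was not tested. Of 19 pan-neuronal markers 6 fell, among them KCNC1 (-0.40) and STMN2 (-0.39), and THY1 (0.33) and CELF4 (0.24) rose (3 higher and 6 lower adjusted over the list alone). Of 15 microglial markers CD74 (0.23) rose and TMEM119 (-0.21) did not pass (0 higher and 0 lower adjusted over the list alone). TF, CNP, NTRK2, AQP4, HBBA, IFRD1, THY1, CELF4 and CD74 lay below 0 with median centring in place of loess, and the software's processed signals put S100B and CLDN5 above 0. Processed signals gave a mean more than 1.5 times smaller for MBP, ASPA, GLUL, GJA1, NTRK2, AQP4, VWF, CA2, KCNC1 and CELF4.

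In the choroid plexus list, of 14 members, PRLR (0.32) rose and TEKT1 (-0.26) fell (1 higher and 1 lower adjusted over the list alone). In the list of regional markers 2 of 23 rose, DLX5 (0.31) and CALB2 (0.21), and 5 fell, GATA3 (-0.41), CBLN2 (-0.31), LHX8 (-0.30), PVALB (-0.25) and LHX2 (-0.21) (4 higher and 5 lower adjusted over the list alone). The median of that list was 0.017, its mean -0.016 and its test pointed down. None of the 6 pituitary markers passed limma's test, CHGA (-0.062) and the dim SIX6 (-0.050) among them (0 higher and 0 lower adjusted over the list alone). Of 12 pineal and photoreceptor markers the channel subunit CNGA3 (-0.35) fell and the retinal opsin RGR (0.79) did not pass (0 higher and 1 lower adjusted over the list alone). PRLR, DLX5 and CALB2 lay below 0 with median centring in place of loess, and the software's processed signals put PVALB above 0. The mean was, in the processed signals, more than 1.5 times smaller for TEKT1, CALB2 and CBLN2 and larger for GATA3, LHX2 and CNGA3. Median centring left the kept probes with medians of -0.30 in females and -0.39 in males, and 5.57% of its calls were higher, against 36.0% with loess.

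**Figure D3:**
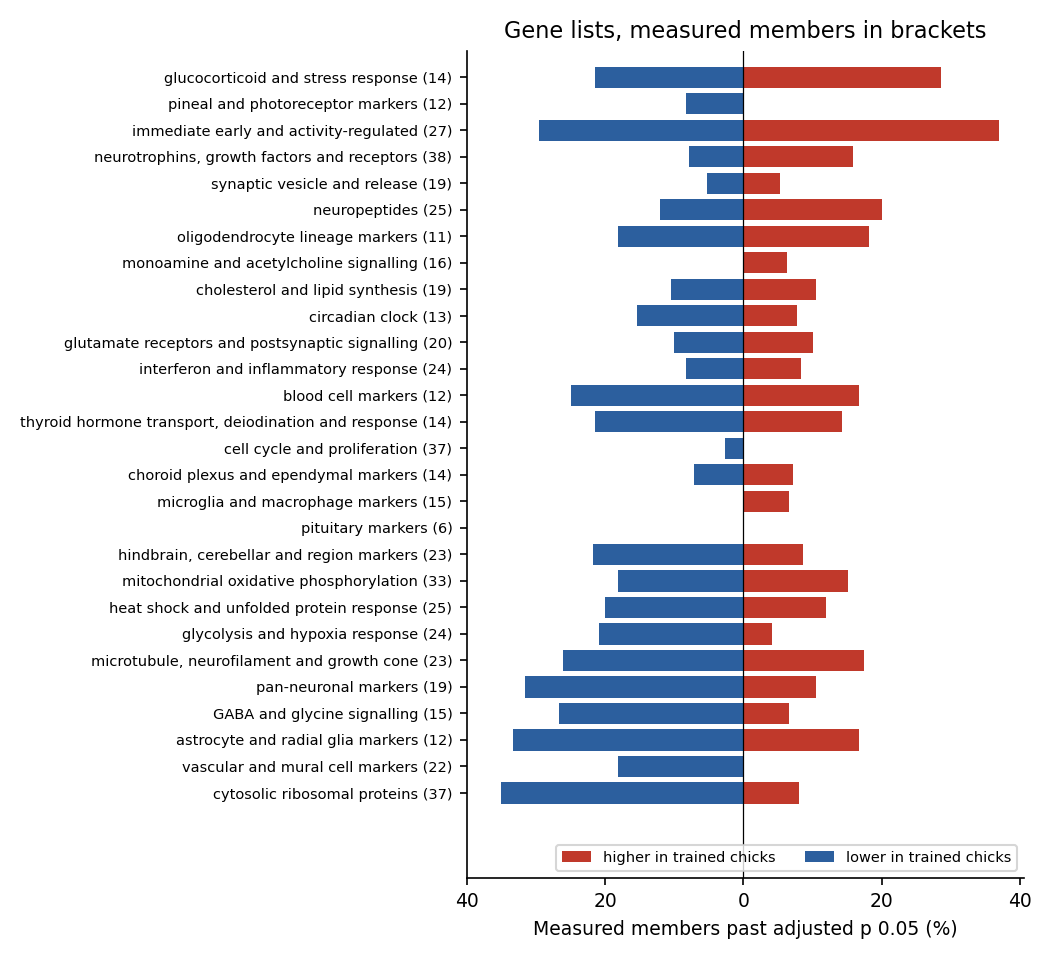
Share of the measured members of each gene list (x axis, percent) that were higher (red, to the right) or lower (blue, to the left) in trained chicks at limma's adjusted p of 0.05, with the number measured in brackets and lists ordered by mean log2 ratio. The cytosolic ribosomal proteins, with 13 lower and 3 higher members of 37, have the lowest mean, and median centring turns those 3 members below 0.

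The responses of the sexes were then set side by side, from a single array each and without a replicate of either sex. In females 88 probes were at least 1.5-fold higher and 176 lower after training, and in males 93 were higher and 262 lower. DIO2 had log2 ratios of 0.99 and 0.89 in females and males, DIO3 -0.67 and -0.63, SIK1 1.12 and 0.88 and EGR1 0.65 and 0.47. The next ranking covers genes with a symbol that were well above background in both channels on both arrays. Among them the largest male excess was in the retinal opsin RGR, at -0.011 in females and 1.60 in males, followed by NDUFB1 (-0.22 and 1.11), the uridine phosphorylase UPP1 (-0.65 and 0.66), LMBR1 (-0.056 and 1.12) and THOC7 (-0.72 and 0.43). Among the same genes the largest female excess was in the phosphomannomutase PMM2, at 1.06 in females and -0.29 in males, followed by KBTBD3 (0.61 and -0.51), CDIN1 (0.71 and -0.14), CYR61 (-0.18 and -0.96) and BTBD7 (0.51 and -0.25). The processed signals gave -0.18 and 3.65 for RGR, -1.45 and 2.39 for THOC7 and 0.92 and -0.85 for KBTBD3, differences more than 1.5 times as large.

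Across the kept probes, which are not independent replicates, female and male ratios correlated at Pearson's r = 0.67 and Spearman's rho = 0.64, and 71.9% of probes had the same sign. Of the probes at least 1.5-fold on both arrays 114 went the same way, 32 higher and 82 lower, and 6 went opposite ways. With the sign of the male array turned, limma called 0 probes (72 at an unadjusted p under 0.05). That fit calls what differs between the arrays, but a shift they share counts as its spread. Its 0 calls therefore do not show that the sexes responded alike. The scanner software's spot-level p, which covers technical error alone, was under 0.01 for 492 higher and 484 lower probes in females and for 569 and 730 in males. In the processed signals r was 0.37, with 483 probes the same way and 96 opposite ways.

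The last comparison set males against females within each condition, which also checks the sex labels. Genes known from the female-specific W chromosome marked the female pools: HINTW was at least 312-fold higher in females, HNRNPKL at least 15.9-fold and UBE2R2L at least 2.24-fold, each not well above background in males. A probe named WPKCI-8, which the array describes as the female-associated factor FAF, was at least 6.58-fold higher. The array describes the HINTW probe as WPKCI-8. Whether the 2 probes read the same gene was not determined, so they are not taken as separate genes. The filamin FLNC was 1.81-fold and transferrin, TF, 1.63-fold higher in females. Males had more MRPL50 (2.40-fold), TMOD1 (2.28-fold), MBLAC2 (2.04-fold), NDUFS4 (2.02-fold), XPA (2.01-fold) and NUDT2 (1.93-fold). Probes placed on Z, of which males carry a pair, had a median male minus female log2 difference of 0.22 in trained and 0.24 in dark-reared chicks over 558 probes, above each of 2000 random sets matched on intensity. The median was -0.011 and -0.0049 over 21631 autosomal probes.

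In both conditions 170 probes were at least 1.5-fold higher in males and 51 in females, and 5 went opposite ways. Of the male-higher probes 79 were placed on Z or W. The 62 probes that galGal2 places on W had male-higher medians of 0.34 and 0.41, and MBLAC2 is one of them, but males carry no W, so these placements are in doubt. No test was made, since each sex had 1 pool per condition and its own array. In the processed signals the Z median over both conditions was 0.45, with 542 probes higher in males and 244 in females.

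**Figure D4:**
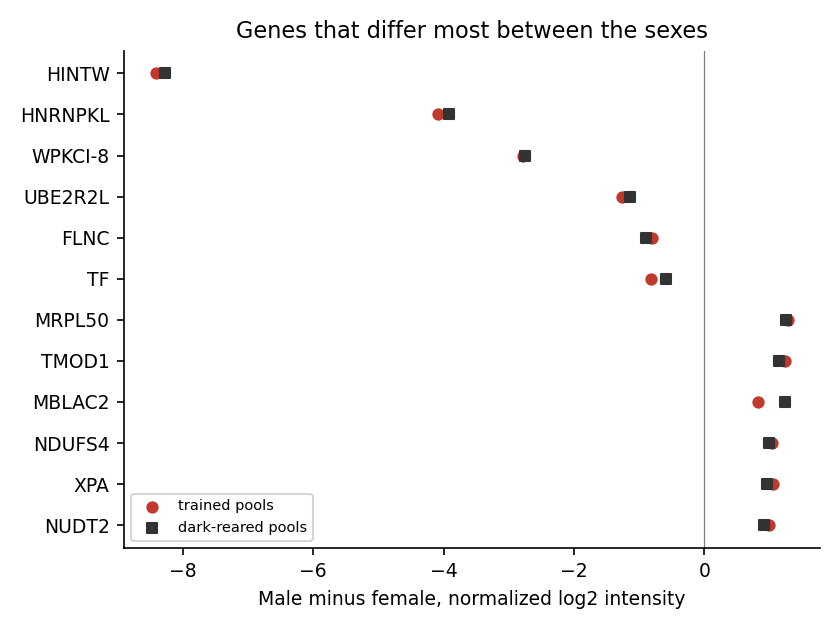
Male minus female difference in normalized log2 intensity (x axis) for the 12 gene symbols named in the comparison of the sexes, with circles for the trained and squares for the dark-reared pools. HINTW lies at -8.42 and -8.27, and MRPL50 at 1.28 and 1.24.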

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

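The test of photoreceptor genes without RGR, the brightness asked of the lens and pigment epithelium markers and the test of intensity for the ribosomal protein genes were chosen after the results were seen. Sex differences stand here because the female and the male array had opposite signs, and neither sex had a replicate array to test them.

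Many probes shifted alike on both arrays. Ratios of different, non-overlapping probes of a gene correlated across arrays at 0.12 over 648 genes, lower than the same probes by 0.60 (95% bootstrap interval 0.52 to 0.68), which argues against a change of the whole transcript as the source of all of the agreement. A probe-specific dye or hybridisation effect as the source of all of it stays open, since the interval of 0.041 to 0.21 spans the bounds of 0.1 and 0.2 set before. Training stays open for single genes, because the trained pools had the same dye on both arrays.

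RGR was higher in trained males, with a male minus female difference of 1.61. In the trained channel its male spot had a pixel spread at percentile 34.1 of 2104 spots of like brightness. This argues against a spot damaged unevenly in that channel. The dark-reared channel was not examined, and probes with an outlier flag had been left out before. The 16 measured lens and pigment epithelium markers had a male median of 0.0017, at percentile 44.9 of random lists and under the bound of 0.1 set before. Their female median was higher, 0.071 at percentile 95.2. Only 4 were as bright as the median gene, SERPINF1 (0.0092 in males), STRA6 (0.24 in males, 0.29 in females), RDH5 (0.018 in males) and LRAT (-0.089 in males), whose level without eye tissue could hide a small share. In males RPE65 (0.24) and RLBP1 (0.35) lay above 0, so eye tissue in the trained male pool stays open. The 11 other pineal and photoreceptor markers had a median at percentile 99.2 in males and 17.6 in females, but the shift of the whole list had been seen before this test. CNGA3, the only member past limma's test, was lower on both arrays (-0.37 in males). Pineal or retinal photoreceptor tissue in the trained male pool therefore cannot be told apart from a response to training. A response that differs between the sexes stays open, since neither sex had a replicate array.

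Ribosomal protein genes were lower as a list in trained chicks, with 13 of 37 members lower and 3 higher, and the call was lost in another setting (adjusted p = 0.999 with an estimated correlation). That camera setting had 1 residual degree of freedom per probe and left no list with an adjusted p under 0.999, so the lost call does not decide. Of random lists matched on intensity 4.50% had a median as low for the mean of the arrays, 0.450% in females and 6.99% in males, and with median centring the list stayed lower (mean -1.04, where the means of all 28 lists lay below 0), so intensity-dependent normalization cannot be told apart from a change. The 13 called lower genes had 1 other probe, at 0.0530, too few to decide on a probe-specific dye or hybridisation effect. An effect of training stays open and shares its direction with the dyes.

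In other named genes the male minus female difference was 1.33 for NDUFB1, 1.31 for UPP1, 1.18 for LMBR1, 1.15 for THOC7, 0.23 for CHGA and 0.10 for SIX6, with the female ratio below and the male ratio above 0. It was -1.35 for PMM2, -1.12 for KBTBD3, -0.85 for CDIN1, -0.76 for BTBD7, -0.17 for JUN and -0.0526 for ARC, with the female ratio above and the male ratio below 0. None of these gene differences was called by limma as reported with the male sign turned, and neither sex had a replicate array. That fit called 0 of all kept probes, so the missing calls do not decide on these differences.

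List medians also had opposite signs in the sexes, without a test. The male minus female difference in the median was 0.19 for the list of pineal and photoreceptor markers, 0.14 for the list of pan-neuronal markers, 0.0890 for the list of glucocorticoid and stress response, 0.0816 for the list of mitochondrial oxidative phosphorylation, 0.0769 for the list of cholesterol and lipid synthesis, 0.0543 for the list of blood cell markers and 0.0113 for the list of pituitary markers. It was -0.20 for the list of astrocyte and radial glia markers, -0.11 for the list of interferon and inflammatory response, -0.0853 for the list of choroid plexus and ependymal markers, -0.0608 for the list of hindbrain, cerebellar and region markers, -0.0606 for the list of neuropeptides, -0.0451 for the list of thyroid hormone transport, deiodination and response, -0.0366 for the list of GABA and glycine signalling, -0.0281 for the list of microglia and macrophage markers and -0.0163 for the list of circadian clock.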

How the results depend on the processing

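The combined settings with the processed signals were chosen after seeing the data. Over both arrays, the numbers of probes higher and lower in trained chicks, 1726 and 3074 as reported, stayed within 1.5 times without background subtraction (2128 and 3402), without the filter on dim probes (2020 and 3465), with the both-channel filter (1664 and 3006), with an intensity trend (1800 and 3108), with robust moderation (1933 and 3312) and with outlier spots kept (1725 and 3073). They were 306 and 628 with normexp offset 16, 974 and 16499 with median centring, 678 and 862 with one value per gene, which tests fewer items, 2866 and 4434 at adjusted p 0.10, and 3074 and 1726 with both signs turned, which reverses each gene by construction. Limma called 0 and 0 with the processed signals and with the series matrix values, which are the same ratios (4878 probes at an unadjusted p under 0.05, smallest adjusted p 0.261). The processed signals gave 0 and 0 with the both-channel filter (smallest adjusted p 0.205), 0 and 0 over the brighter probes (0.0731) and 811 and 753 with an intensity trend. Except for the settings whose construction explains the change, the cause was not tested.

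Of 161 named genes 143 passed as reported. With normexp offset 16 87 no longer passed and 0 reversed, and with the processed signals 0 of the 143 passed, 127 with their sign kept and 16 with it changed. In the processed signals and in the series matrix values the means were S100B (0.10), CENPF (0.073), HMGCS1 (0.082), MVD (0.030), GABRA3 (0.076), GAD1 (0.10), IFI35 (0.012), NTS (0.054), IGFBP4 (0.090), NCOR1 (0.017), CLDN5 (0.053), GAPDH (0.034), PVALB (0.0061), CHGB (0.25), TGFB3 (0.095) and NCOA1 (0.13). With median centring 55 genes changed sign, among them, with their means, MT4 (-0.11), YWHAE (-0.20), FKBP5 (-0.12), ZSWIM5 (-0.089), NTRK2 (-0.39), HBBA (-0.53), IFRD1 (-0.48), FDPS (-0.42), PRLR (-0.14), NR1D2 (-0.17), CRH (-0.27), CACNG3 (-0.71), CAMK2B (-0.48), PGAM1 (-0.46), PDIA3 (-0.28), DLX5 (-0.42), NFKB2 (-0.13), SOCS1 (-0.11), CD74 (-0.60), DRD5 (-0.54), CCK (-0.26), PDGFB (-0.29), BDNF (-0.15), NTRK3 (-0.36), TF (-0.53), CNP (-0.53), THY1 (-0.40), DNM1 (-0.33), SYT4 (-0.57), CRYM (-0.70), NDUFB1 (-0.21), UPP1 (-0.49), KBTBD3 (-0.26), BTBD7 (-0.32), AQP4 (-0.55), RPL3 (-0.56), RPLP2 (-0.66), RPL35A (-0.78), SGK1 (-0.54), HSPA9 (-0.59), HERPUD1 (-0.20), CALB2 (-0.55), DCX (-0.49), NCAM1 (-0.13), TUBB4B (-0.71), MAP1A (-0.76), NDUFA9 (-0.58), NDUFB6 (-0.62), NDUFA5 (-0.64), NDUFAB1 (-0.67), ADCYAP1 (-0.10), GRP (-0.65), PCSK2 (-0.35) and CELF4 (-0.41). Median centring left the kept probes with medians of -0.30 in females and -0.39 in males. Its sign changes are therefore against 0 and not against the typical kept probe. Each array alone is 1 of 2 values behind a mean, so leaving either out tests nothing. Of values past the threshold in neither setting 52 changed sign. The cause was not tested.

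In females 164 and 278 probes were at least 1.5-fold higher and lower with offset 16, 737 and 1008 with the processed signals or series matrix values and 15 and 6878 with median centring. In males these were 218 and 426, 831 and 1298 and 12 and 9674. At 2-fold they were 15 and 7 in females and 14 and 10 in males, and with a spot p under 0.01 as well 74 were lower in females and 117 in males. Pearson's r and Spearman's rho between the arrays were 0.68 and 0.68 without background subtraction, 0.59 and 0.60 with offset 16, 0.37 and 0.43 with the processed signals or series matrix values, 0.91 and 0.91 with median centring, 0.62 and 0.51 without the filter and 0.68 and 0.66 with the both-channel filter. Probes 1.5-fold in the same direction were 483 with the processed signals or series matrix values and 6461 with median centring, and 5 at 2-fold. Those in opposite directions were 12 with offset 16, 96 with the processed signals or series matrix values and 1 at 2-fold, and offset 16 gave 2 calls with the male sign turned. The cause was not tested.

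Median centring called 10 lists and an estimated inter-gene correlation 0 (camera, with the ribosomal mean still -0.17 and its p unadjusted 0.140). With median centring the mean of each of the 28 lists lay below 0, and camera called 3 lists whose mean had been above 0 as higher than the other genes, the list of interferon and inflammatory response (-0.23), the list of monoamine and acetylcholine signalling (-0.17) and the list of pineal and photoreceptor markers (-0.057). Between the sexes, the median differences over both conditions were 0.45 for Z and 0.70 for W with the processed signals, and 0.13 and 0.22 without the filter. Probes higher in males were 542 with the processed signals and 283 in the dark-reared channel alone. Those higher in females were 244 with the processed signals, 85 in the trained and 91 in the dark-reared channel alone, where 1 condition is asked in place of both. Signal over background limits dim probes, whose ratios the offset shrinks. The cause was not tested.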

Other observations

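The counts in this part were chosen after the data were seen. Of 648 genes with non-overlapping probes 177 had at least 1 probe past limma's adjusted p of 0.05, and 19 had both past it. Of all kept probes 17.5% passed, and the number of such pairs expected by chance was not computed. A pair past the test is therefore not taken as support for its gene. Both probes were lower in 10 genes: the splicing kinase CLK4 (-0.86 and -0.57), the splicing regulator SFSWAP (-0.49 and -0.42), the microtubule regulator STMN2 (-0.39 and -0.36), the dynein heavy chain DYNC2H1 (-0.48 and -0.30), ADGRB3 (-0.25 and -0.35), BMS1 (-0.24 and -0.24), PSMA2 (-0.24 and -0.40), MND1 (-0.23 and -0.35), CTTNBP2 (-0.34 and -0.23) and LMO7 (-0.28 and -0.21). Both were higher in 6 genes, EXTL3 (0.48 and 0.40), TMEM63C (0.38 and 0.49), CMIP (0.30 and 0.42), CRYM (0.26 and 0.45), SEMA3G (0.29 and 0.23) and MAP1A (0.21 and 0.29). The probes of CASKIN1 (-0.31 and 0.22), DDX54 (-0.29 and 0.41) and PAM (0.23 and -0.30) passed in opposite directions. In the processed signals at least 1 of the lower probes of STMN2, DYNC2H1, BMS1, MND1, CTTNBP2 and LMO7 lay above 0, and median centring put at least 1 of the higher probes of EXTL3, CMIP, CRYM, SEMA3G and MAP1A below 0. Of the genes with opposite probes, DDX54 had both above 0 in the processed signals, and CASKIN1 and PAM had both below 0 with median centring.

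Among probes without a gene symbol, the largest female excess over both conditions was at least 45.3-fold, with the male pools not well above background. Another probe, well above background in both sexes, was 26.3-fold higher in females.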
